A study of Mus musculus and Gallus gallus with 19 samples.

How the data were processed

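Single-cell libraries were made with the 10x Chromium 3' chemistry from trypsin-dissociated distal limb buds of littermates, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 3.0.0 against mm10, per the submitters' processing notes and the file headers. The settings of cell calling are not given in the sources used here. The deposited peak lists give position and a peak score. Their peak names carry the name of the MACS caller, per the deposited files, and its version and settings for these lists are not given in the sources used here. CASAVA 1.4 and Bowtie 1.0.0 are named for the mouse lists, with mm9, and for the chicken lists, per the submitters' processing notes. The build of the chicken lists is not given in the sources used here. What the score measures is not stated in the files, and it was used to rank or filter peaks within a list. An added alternative alone set 2 lists to the higher of their lowest scores, which takes their scores to be on a common scale. WT H3K27ac and H3K27me3 lists are the authors' pooled lists of 2 samples each, the first reanalysed from another series. The lowest scores were 80 in the WT and 50 in the SPDH H3K27ac list. The 8 spike-in samples were not analysed here. No genome annotation of the mm9 build was used here, so peaks were not joined to genes. Gene coordinates and chromosomes come from the RefSeq table of GRCm38, the build of the expression data, in which 25200 of 31053 symbols matched.

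Barcodes were kept with at least 1000 detected genes, at most 10% mitochondrial UMIs and fewer UMIs than 4 times the library median. This left 4545 WT and 4195 SPDH cells. Scrublet called 1 cell in each library (0.022% in WT and 0.024% in SPDH), which means that doublet calling did not work here. Those cells were removed, leaving 4544 and 4194 with medians of 11081 and 10510 UMIs. As a substitute, the 4% of cells with the highest doublet scores were removed in an added alternative. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were found per library and merged, without mitochondrial, hemoglobin and sex-linked genes. The steps after that were 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0, without integration (scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15). Clusters took a class name from marker lists fixed beforehand. The name went to the class with the highest mean log2 fold of its markers, with at least 3 markers raised 1.5-fold in 10% of cells and no other class holding more of the top 10 genes. Some named clusters were led by cell cycle genes. Mesenchyme-like cells are all cells outside clusters named muscle, ectoderm, endothelium, pericyte, erythroid, immune or Schwann.

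Several choices were made after values had been seen. The number of Leiden iterations was not fixed beforehand. Clustering was first run with 2 iterations, the shares were seen to shift with small changes, and it was then run to convergence. No repeat of the convergence run with other seeds is reported here, so whether it is steadier is not shown. The first setting is reported and the second is an added alternative, as are 10 other random seeds. The naming rule and its thresholds were written after the marker levels of the first clustering had been viewed. The mesenchyme-like group is wider than the classes first planned, because clusters led by cell cycle genes carry no class name; an added alternative keeps the named classes alone (4776 of 8452 cells). The floor of 100 UMIs for genes left out of clustering, the common score minimum for peak lists and the second set of clusters for a fixed mix were also added. The lists of 10000, 5000, 2000 and 1000 chicken peaks were added once the lists had been opened. A few genes outside the naming rule are given and named as chosen after their values were seen. The escape genes Ddx3x, Kdm5c, Utp14a and 5530601H04Rik, the last of which is absent from the gene table under that symbol, were fixed before their values were seen, though after genes differing by 1.5-fold or more had been listed.

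UMIs were summed over the cells of a class per library and scaled to 1000000 per library (CPM). The ratio of SPDH over WT has an exact 95% interval for 2 Poisson counts (Clopper-Pearson, scipy 1.17.1). With 1 library per genotype there is no test, and intervals cover counting error only. The sums hold 53243180 UMIs in WT and 46720516 in SPDH for mesenchyme-like cells. Genes are named by a rule fixed before the data were examined. It takes Hoxd13 and the posterior Hoxd list, then the 10 highest and 10 lowest ratios among genes with at least 50 CPM in either library and 100 UMIs in all, without mitochondrial, hemoglobin and sex-linked genes. From each fixed list it takes up to 4 members with the largest ratio, and from each class with at least 50 cells in each library the 5 highest and 5 lowest genes. Some genes that the rule names are not reported here. List medians used members with at least 10 CPM and a pseudocount of 0.5 UMIs, and were ranked among 10000 random lists of like size and expression, as a description of these libraries. Each list percentile describes these 2 libraries alone.

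Peaks were called shared when they overlapped by at least 1 bp, with exact binomial intervals, and 100 random relocations within chromosomes gave the background. HOXD13 sites come from a third-party list of E11.5 limb buds that the authors reprocessed. The alternatives changed cell filters, doublets, resolution, variable genes, scaling, depth, cluster mix, list filters, overlap, score thresholds and peak numbers. Others took the list of each chicken WT replicate in place of the merged list. The ratio step was tested on simulated counts for the comparison of SPDH with WT over all cells, with 200 changed genes. Intervals held the true ratio for 94.6% of 3175 unchanged genes, and for 98%, 98%, 96% and 92% of 50 genes each at folds of 0.5, 0.67, 1.5 and 2.0. All 20 extreme genes of 3410 were changed ones. The simulation held counting error alone, with no spread between embryos or libraries. Its folds were also larger than those of most extreme genes in mesenchyme-like cells. It therefore does not show that the genes named here differ by genotype. Of 200 unchanged lists, 4% passed the outer percentiles. These lists were drawn at random from the same genes that they were ranked among, so a share near this was set by the design. It does not show how lists of genes that vary together would rank. Overlaps were checked against a direct comparison of simulated intervals.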

Results

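The series holds 19 samples from E12.5 mouse limb buds and from chicken limb micromass cultures, which are dense cultures of limb mesenchyme that form cartilage. It compares wild-type (WT) tissue with the Spdh mutant (SPDH), a mouse model of synpolydactyly that carries a lengthened alanine tract in the limb transcription factor HOXD13. Single-cell RNA sequencing was made from the distal limb buds of 1 WT and 1 homozygous embryo. The WT library held 5027 barcodes and 58039161 UMIs (unique molecular identifiers, each counting 1 captured RNA), and the SPDH library 4628 barcodes and 50999610 UMIs. The median was 10405 UMIs per barcode in WT and 9910 in SPDH. Peak lists of H3K27ac, a mark of active enhancers and promoters, and of H3K27me3, a mark of Polycomb repression, covered 2 pooled samples in WT and 1 in SPDH. Chicken cultures expressing tagged HOXD13 gave 2 WT samples and 1 SPDH sample. The 8 samples with a Drosophila spike-in were not analysed here. No expression comparison has a replicate, so no test was made, and every interval for expression and cell shares covers counting error only.

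The clusters named as non-mesenchymal were small in both embryos, and the cells outside them are called mesenchyme-like. Muscle-like cells, named from genes such as Myod1 and Myog, made up 1.47% of 4544 kept WT cells (95% exact binomial interval 1.14 to 1.87) and 1.12% of 4194 kept SPDH cells (0.825 to 1.49). Immune-like cells were 33 in WT and 29 in SPDH, erythroid-like cells 21 in each library (25 and 44 when cells with at least 500 genes were kept), ectoderm-like cells 13 and 19, endothelium-like cells 13 and 14 (112 and 86 when SPDH cells were assigned to WT clusters), and Schwann and neural crest-like cells 2 and 7. The larger endothelium-like number was seen in that setting alone, against 20 and 15 with cells of at least 500 genes. The same 4544 kept WT cells entered the main clustering and that setting, so its cluster took in WT cells beyond the 13 called endothelium-like in the main clustering. Which cells these were was not tested. Among mesenchyme, the class sizes compared here come from a clustering that left out the genes differing by 1.5-fold or more between the libraries. In that clustering, chondrogenic-like cells were 653 in WT and 578 in SPDH, a difference of -0.59 percentage points (interval -2.06 to 0.888). Distal interdigital-like cells were 485 and 434, tendon and connective tissue-like cells 740 and 714, and proximal-like cells 129 and 127. The clusters without a class name held 52.6% of cells in each library, but some of them differed, in opposite directions. The cluster led by Spp1 and Shisa3, with Sfrp2 and Gdf5 among its leading genes, held 4.56% of WT cells (3.97 to 5.20). In SPDH it held 7.92% (7.12 to 8.77). A cluster led by Ube2c and Cenpf held 10.7% in WT (9.79 to 11.6) and 8.44% in SPDH (7.62 to 9.32). For tendon and connective tissue-like cells the difference was 0.74 points (interval -0.84 to 2.32), and 1.83 points (0.201 to 3.46) with the differing genes kept. It was above 0 under each setting tried, from 0.795 to 2.12 points over 10 other random seeds. All settings regroup cells of the same libraries. The interval included 0 under several, such as with cells of at least 500 genes (1.21 points, -0.253 to 2.68). It also did with SPDH cells assigned to WT clusters (1.31 points, -0.174 to 2.81), and under other settings it lay above 0. When the differing genes were kept among the variable genes, as first planned, chondrogenic-like cells came to 741 and 500. This was a difference of -4.39 points (interval -5.85 to -2.91), and with 10 other random seeds of the same clustering it ran from -5.88 to -0.061 points. It was -3.30 with cells of at least 500 genes, -3.67 with at least 2000 and -2.13 with SPDH cells assigned to WT clusters, each interval below 0. A resolution of 2.0 gave -0.42 (interval -1.73 to 0.904). A Leiden resolution of 0.5 gave +4.38 points. Distal interdigital-like cells, with the differing genes kept, differed by -0.25 points (interval -1.95 to 1.45), and from -4.02 to 3.11 over 10 other seeds. Their difference was -4.20 (-5.95 to -2.45) at a resolution of 0.5 and -2.45 (-4.07 to -0.82) at 2.0. For proximal-like cells it was -1.80 (-2.92 to -0.68) with SPDH cells assigned to WT clusters. In the clustering without the differing genes the intervals of the 4 class differences included 0. The genes left out were picked from these same libraries. They included Irx1 and Inhba, which led a chondrogenic-like cluster of 243 WT and 85 SPDH cells when kept. Leaving them out can itself bring the class sizes closer together, so these intervals do not decide whether the shares differed.

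Hoxd13 itself was expressed in both libraries. In mesenchyme-like cells (4395 in WT and 4057 in SPDH) it reached 220 CPM (UMIs per 1000000 of the same cells) in WT and 191 in SPDH, a log2 ratio of -0.21 (interval -0.25 to -0.17). Spdh alters the protein sequence, so a count of 3' tags does not check the genotype label. The neighbouring posterior Hoxd genes differed little. Hoxd12 had a log2 ratio of 0.03, Hoxd11 of -0.11, Hoxd10 of -0.05, Hoxd9 of -0.18 and Evx2 of -0.04. The median of the list was -0.08, at percentile 0.62 of 10000 random lists matched on expression, and with the mix of mesenchyme clusters held fixed Hoxd13 stood at -0.11, or at -0.075 over clusters made without the differing genes. The posterior Hoxa genes leaned the other way. Hoxa13, the partner of Hoxd13 in digit formation, had a log2 ratio of 0.48 and the long non-coding RNA Hottip, which lies beside it, 0.75. The list median was 0.13 at percentile 99.5, and with members of at least 50 CPM it was 0.056, inside the random range.

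Aldh1a2, the enzyme that makes retinoic acid in the interdigital tissue, had the lowest ratio in mesenchyme-like cells among 3466 genes of sufficient level. It measured 70.0 CPM in WT (3725 UMIs) and 31.2 in SPDH (1457 UMIs), a log2 ratio of -1.17 (interval -1.25 to -1.08), or 2.24-fold lower. It lies on mouse chromosome 9 between 71215789 and 71296243 (GRCm38). The remaining 9 lowest genes were Lhx2 (-0.51), Creb5 (-0.49), Sulf1 (-0.47, or -0.82 when unnamed clusters were left out), Pth1r (-0.44), Tgfb2 (-0.42), Msx2 (-0.40), Msx1 (-0.31), Gm9493 (-0.30) and Gli3 (-0.29), all as log2 ratios. Msx1 and Msx2 are homeobox genes driven by BMP signalling, Lhx2 is a LIM homeobox gene of distal limb mesenchyme, and Gli3 encodes a transcription factor of the hedgehog pathway. The 10 highest genes were Eif2s3x (0.71), Hist1h2ap (0.52), Pbdc1 (0.52), Anxa2 (0.51), Spry2 (0.48), Nfia (0.47), Sfrp2 (0.43), Ncam1 (0.42), Shisa2 (0.41) and Unc5c (0.40). Sfrp2 encodes a secreted antagonist of Wnt signalling and Spry2 a feedback inhibitor of FGF signalling. Hist1h2ap belongs to a histone gene family of near-identical copies, so its count is uncertain. Of the 3466 genes, 99.9% lay within 1.5-fold. The sex of the embryos differed. Xist, the RNA of the inactive X chromosome, had 0.142 CPM over all kept cells in WT and 1015 in SPDH. The Y-linked gene Ddx3y had 65.2 in WT and 0 UMIs in SPDH, at least 1070-fold higher in WT against a floor of 3 UMIs. Eif2s3x and Pbdc1 are X-linked, so genotype and sex are mixed in every ratio given here.

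**Figure D1:**
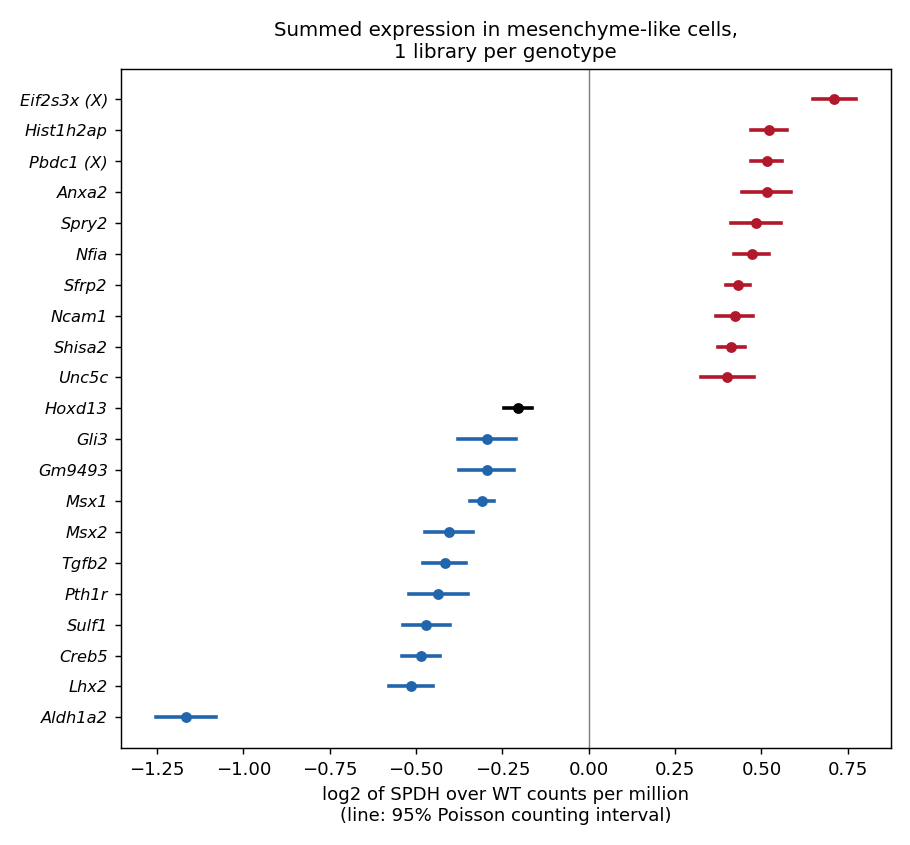
Log2 ratio of SPDH over WT CPM (horizontal axis) in mesenchyme-like cells for the 10 highest genes (red), Hoxd13 (black) and the 10 lowest genes (blue), with 95% Poisson counting intervals as lines; X marks genes on the X chromosome. Aldh1a2 at -1.17 stands apart from the next lowest gene, Lhx2 at -0.51.

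Aldh1a2 was lower in the classes where it was most expressed in WT. Gene values by class come from the clustering that kept the differing genes, with 927 WT and 845 SPDH distal interdigital-like cells, 741 and 500 chondrogenic-like, 774 and 791 tendon and connective tissue-like, and 112 and 86 proximal-like. In distal interdigital-like cells Aldh1a2 measured 140 CPM in WT and 66.0 in SPDH (log2 -1.09), and in chondrogenic-like cells 99.3 and 31.5 (log2 -1.66). Of the 874 WT and 181 SPDH Aldh1a2 UMIs in chondrogenic-like cells, a cluster led by cell cycle genes such as Nusap1 held 639 and 162. A cluster led by Irx1 and Inhba held 233 and 17. The cluster led by Cytl1 and Matn4, with Acan among its leading genes, had fewer than 20 in all. The class value therefore says little about Aldh1a2 in cells with strong cartilage markers. In tendon and connective tissue-like cells, where Aldh1a2 was low, it measured 12.7 and 14.9 (log2 0.23, interval -0.14 to 0.61). Over the 17 mesenchyme clusters with at least 20 Aldh1a2 UMIs it was lower in SPDH in 12, with the interval below 1 in 8. Over 15 such clusters made without the differing genes it was lower in 11, with the interval below 1 in 9, and higher with the interval above 1 in a cluster led by Nefm and Cavin2 (log2 0.75, interval 0.0011 to 1.55). Hoxd13 measured 206 and 135 in chondrogenic-like cells (log2 -0.61), 357 and 332 in distal interdigital-like cells (log2 -0.11), and 70.8 and 77.6 in tendon and connective tissue-like cells (log2 0.13, interval -0.03 to 0.29).

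**Figure D2:**
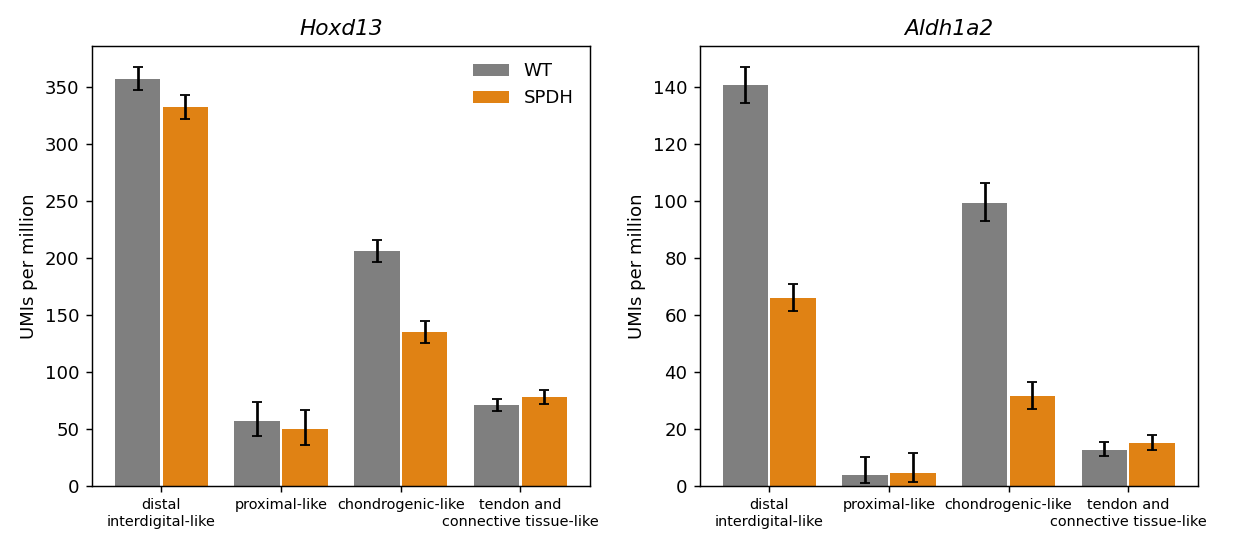
CPM (vertical axes) of Hoxd13 and Aldh1a2 summed over the cells of 4 mesenchymal classes in WT (grey) and SPDH (orange), with 95% Poisson counting intervals. Aldh1a2 is lower in SPDH in the distal interdigital-like and chondrogenic-like classes and not in the tendon and connective tissue-like class. In the chondrogenic-like class most of its UMIs came from a cluster led by cell cycle genes.

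Within each class the genes with the highest and lowest ratios were listed, without a test between classes. Chondrogenic-like cells had lower Irx1 (log2 -2.36), Msx2 (-1.40), Papss2 (-1.02) and Msx1 (-0.92), besides Aldh1a2, and higher Shisa3 (1.61), Hist1h2ap (0.91), Dlk1 (0.83), Lockd (0.78) and Rprm (0.78). A cluster led by Irx1 and Inhba held 243 of the 741 chondrogenic-like WT cells and 85 of the 500 SPDH cells in the clustering with all variable genes, so the class averages weigh it differently. Another cluster of this class, with 360 WT and 299 SPDH cells, was led by cell cycle genes such as Nusap1, Mki67 and Top2a. Distal interdigital-like cells had lower 1190002N15Rik (-0.68), Tbx18 (-0.68) and Ctsc (-0.65), and higher Evx1os (0.99), Unc5c (0.88), Ebf1 (0.87) and Meg3 (0.85). The make-up of this class also differed, with 296 WT and 368 SPDH cells in a cluster led by Aldh1a2 and Cbln4, and 294 and 185 in a cluster led by Ung and Gja3 that also had the S phase gene Cdc6 among its leading genes. Tendon and connective tissue-like cells showed smaller differences among their lowest genes, Cep44 (-0.55) and Cited1 (-0.41) the first of them. Their highest genes included Egr1, an immediate early gene (1.91), Nefm (0.82), the X-linked Eif2s3x (0.67) and Anxa2 (0.66). Proximal-like cells, with 112 WT and 86 SPDH cells, had the shallowest sums. Their extremes were Nbl1 (-1.22), Lix1 (-1.18) and Sostdc1 (-1.03) on the lower side, and Zfp358 (0.93), Tpst1 (0.91) and Eif2s3x (0.88) on the higher side.

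Several lists fixed before the data were examined had medians outside the range of matched random lists in mesenchyme-like cells, by small amounts. Members with at least 10 CPM entered each median. The interdigit and cell death list had a median log2 ratio of -0.08, percentile 0.01, with 8 of 13 members below 1 beyond their counting interval and 3 above, among the latter Igfbp5 at 0.33. Of 13 tendon and connective tissue genes, 11 lay above 1 beyond their interval, with Lum at 0.38, Col3a1 at 0.36 and Col6a1 at 0.30, while Tgfb2 was at -0.42. The list median was 0.22, percentile 100. It was 0.075 with the mix of mesenchyme clusters held fixed, 0.086 with the 6 members of at least 50 CPM and 0.29 when unnamed clusters were left out. The joint list (median 0.15, percentile 99.8) and the Wnt pathway list (0.08, percentile 99.6) shared Sfrp2, the highest member of both. Of the 7 measured joint genes 5 were higher and 2 lower, with Sulf1 at -0.47. Of the 12 measured Wnt genes 7 were higher and 5 lower, among the latter Tcf7 (-0.28) and Frzb (-0.24). With the mix held fixed both lists came inside the random range, the joint list at 0.053 (percentile 90.2) and the Wnt list at 0.043 (percentile 94.3). The hedgehog pathway list had a median of 0.10 at percentile 98.8, with Grem1 at 0.42 and Gas1 at 0.21 against Gli3 at -0.29. Its median was 0.20 with the 3 members of at least 50 CPM, all of them higher, and 0.18 without a filter. The cut at 50 CPM left out Gli3, at 47.6 CPM over both libraries. S phase genes had a median of -0.10. Of 20 genes, 18 were lower, 16 of them beyond their counting interval, such as Pcna (-0.29) and Cdc45 (-0.24). With the mix held fixed the S phase median was -0.041. G2 and M phase genes were at -0.05, with 18 of 20 lower and 11 below 1 beyond their interval. Their median turned to 0.041 with the mix held fixed.

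Other lists stood inside the range of random lists, some of them outside it under another setting. The retinoic acid pathway had a median of -0.0028 at percentile 35.6, from 10 of its 14 members. Apart from Aldh1a2 these stayed close to 0, such as Cyp26b1 (0.08), Rara (-0.06) and Rarg (-0.05). Rarb, too low to enter the median, was among the genes differing by 1.5-fold or more between the libraries. With the mix held fixed the median was -0.041 (percentile 2.64), with 8 of the 10 lower. The BMP pathway was at -0.02 (percentile 9.46), or -0.084 (percentile 0.14) with members of at least 50 CPM, with Msx2 and Msx1 lower and Grem1 (0.42) and the X-linked Chrdl1 (0.39) higher. FGF response genes were at -0.03 (percentile 6.0), or 0.075 (percentile 98.9) with members of at least 50 CPM. Cartilage genes were at 0.01 (percentile 71.7), at 0.073 (percentile 99.8) with the mix held fixed and at -0.16 (percentile 0) when unnamed clusters were left out, and hypoxia and glycolysis genes at -0.03 (percentile 12.0), or -0.052 (percentile 1.79) without unnamed clusters. Of the cartilage collagens, Col9a2 was at 0.26, Col9a1 at 0.22, Col2a1 at 0.13 and Col27a1 at -0.12.

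H3K27ac peaks of SPDH limb buds lay mostly within those of WT. The WT list held 12675 peaks over 21126 kb and the SPDH list 10415 peaks over 14538 kb, with mm9 coordinates. An SPDH peak met 72.5% of WT peaks (exact interval 71.7 to 73.3), and a WT peak met 90.9% of SPDH peaks (90.3 to 91.4). Relocating the peaks at random on the same chromosomes gave a mean of 1.28% and 1.57%. The WT peaks that were missing were weak ones. Of WT peaks in the highest of 4 score classes of equal size, 99.9% were met, against 30.2% in the lowest (the scores are the authors', used within the WT list). The WT list pooled 2 samples, reanalysed from another series, and the SPDH list came from 1, so no spread between samples can be set against the difference. H3K27me3 lists had near-equal numbers, 10963 in WT and 10938 in SPDH. An SPDH peak met 72.5% of WT peaks and a WT peak met 73.5% of SPDH peaks, with relocated means of 2.40% and 2.43%.

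Sites bound by HOXD13, in a third-party list of 17965 peaks from E11.5 limb buds, were compared with the E12.5 H3K27ac peaks. The aim was to ask whether acetylation was lost there in the mutant, though the sites are from an earlier stage. A HOXD13 peak was present at 2665 of the WT H3K27ac peaks, of which 71.0% were kept in SPDH, against 72.9% of the 10010 others. The difference of -1.88 points has an interval of -3.84 to 0.055 and a ratio of shares of 0.974. The difference was -2.41 points (-4.29 to -0.566) with a gap of up to 1 kb allowed, -3.33 (-5.91 to -0.816) with the better-scoring 50% of HOXD13 sites and -4.49 (-6.64 to -2.35) with both lists at a common score minimum, and it turned to 2.67 (-1.28 to 6.31) in the better-scoring 50% of each list. WT peaks with a site had a lower median score (214 against 279) and a greater median width (1747 against 1453 bp). Within 4 classes of WT score, peaks with a site were kept as often or more, 35.8% against 28.2% in the lowest and 70.0% against 63.9% in the next. Within 4 classes of WT width they were kept less, 38.4% against 45.8% in the narrowest and 87.6% against 92.1% in the widest. Peaks of SPDH alone had a site in 31.3% of 952 cases (28.4 to 34.4), above the 20.1% of the shared SPDH peaks and the 22.2% of WT-only peaks. This comparison was not repeated within classes of SPDH score or width, so it does not show a gain of acetylation at HOXD13 sites.

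**Figure D3:**
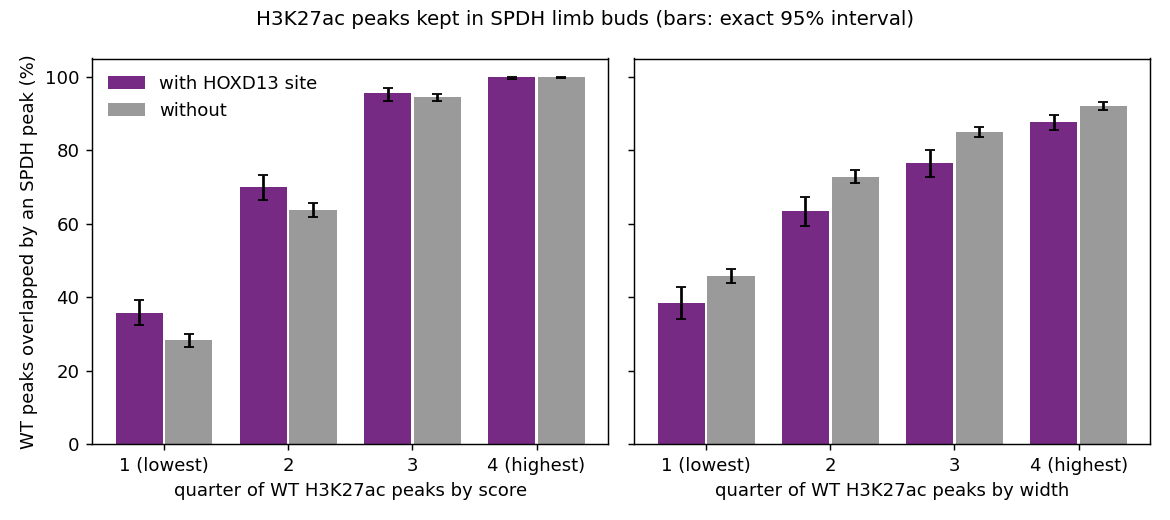
Percentage of WT H3K27ac peaks overlapped by an SPDH peak (vertical axis) in 4 equal classes of WT peaks by score (left) and by width (right), for peaks with a HOXD13 site (purple) and without (grey), with exact 95% binomial intervals. Peaks with a site are kept more often in the lowest score class (35.8% against 28.2%) and less often in the narrowest class (38.4% against 45.8%).

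WT-only H3K27ac peaks were not met by H3K27me3 peaks more often in the mutant. Of the 3484 WT-only H3K27ac peaks, an SPDH H3K27me3 peak met 2.35% (interval 1.88 to 2.91) and a WT H3K27me3 peak 3.44% (2.86 to 4.10), or 6.70% and 8.37% when a gap of up to 1 kb was allowed. Shared peaks gave 1.86% and 2.73%. For SPDH-only H3K27ac peaks the values were 4.41% (3.20 to 5.92) in SPDH and 3.78% (2.66 to 5.20) in WT. An H3K27me3 peak was present in SPDH alone at 18 of the WT-only peaks and in WT alone at 56, and at 30 and 110 of the shared peaks. The SPDH H3K27me3 list covered 27776 kb and the WT list 32179.8 kb.

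In chicken cultures, SPDH peaks overlapped WT HOXD13 peaks less than the WT replicates overlapped one another, when lists of equal length were taken. Among the 12564 best peaks of each list, 52.1% of WT replicate 1 peaks were met by replicate 2 (51.3 to 53.0). The value was 47.4% for WT replicate 1 with SPDH (46.6 to 48.3) and 43.8% for WT replicate 2 with SPDH (43.0 to 44.7). Among the 1000 best peaks the values were 70.0%, 60.8% and 63.1%. SPDH has 1 sample and WT a single pair of replicates, so the spread between pairs is not known. In whole lists, 61.8% of the 14099 SPDH peaks were met by the authors' merged WT list of 25577 peaks, against a mean of 1.36% after relocation. Against the list of WT replicate 2 alone the share was 40.4%, and against that of WT replicate 1 alone 51.0%. These lists are also shorter than the merged list, and equal numbers of best peaks from the SPDH and merged lists gave 50.9%. WT replicate 1 had 18755 peaks and replicate 2 12564.

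**Figure D4:**
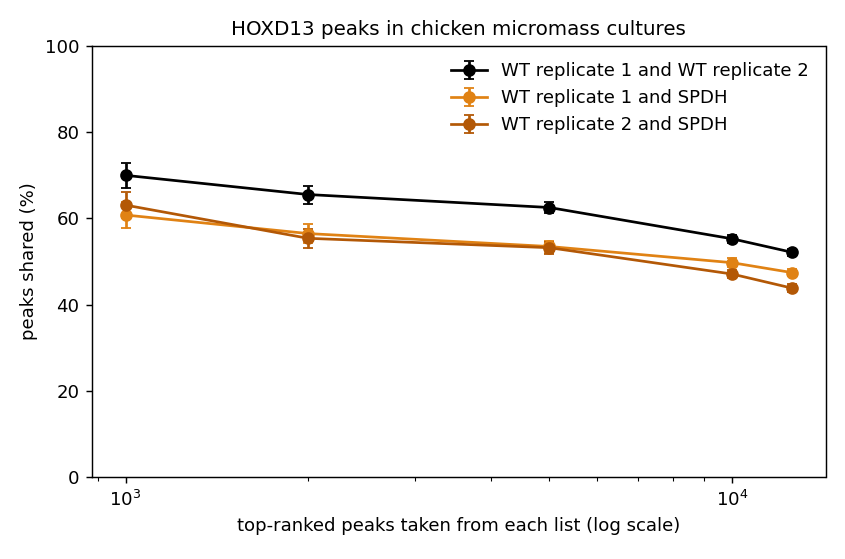
Share of peaks met in the other list (vertical axis, percent) against the number of best-scoring peaks taken from each list (horizontal log axis), for the pair of WT replicates (black) and for each WT replicate with SPDH (orange, brown), with exact 95% binomial intervals. The WT pair lies above both others at each number, 52.1% against 47.4% and 43.8% at 12564 peaks.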

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

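All tests of H3K27ac peaks below, and the count of X-linked genes among the lowest genes, were chosen after the result was seen. Nbl1, which encodes a secreted BMP antagonist, had opposite directions in different classes. Its log2 ratio of SPDH over WT was 0.67 in chondrogenic-like cells (interval 0.42 to 0.92) and -1.22 in proximal-like cells (interval -1.76 to -0.71), a distance of 1.89. The difference was not tested, there being 1 library per genotype. It was the sole gene of this kind among 39 named in the classes, and rests on 118 WT and 44 SPDH UMIs in proximal-like cells.

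The 10 genes with the lowest ratio in mesenchyme-like cells, led by Aldh1a2, had a median log2 ratio of -0.43. A different mix of mesenchyme clusters in the libraries would bring this close to 0 once the mix is held fixed. The median was then -0.41, which argues against the mix as the whole cause. Sex of the embryos cannot be told apart from genotype, since each was measured in the same 1 embryo per genotype, and 0 of the 10 genes being X-linked decides nothing for autosomal genes. A mutant effect on these genes remains possible and untested against embryo or library.

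X-linked Eif2s3x and Pbdc1 were among the 10 highest genes. The sex of the embryos is a candidate explanation. Ddx3x, Kdm5c and Utp14a, X-linked genes that escape X inactivation and were named before their values were seen, had a median log2 ratio of 0.23, while all 115 X-linked genes of sufficient level had a median of -0.01, as did the 3288 autosomal genes. Utp14a alone was at 0.02, and 5530601H04Rik, fixed with these genes, was absent from the gene table under that symbol. These values are consistent with a dose difference at escape genes, not with a general shift of the chromosome.

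WT H3K27ac peaks without an SPDH peak may reflect a less sensitive SPDH list, made from 1 sample against 2 pooled. In the highest of 4 score classes 99.9% of WT peaks were met, which this explanation needs. A loss of acetylation confined to weak peaks would give the same value, so it does not single out this explanation. Preferential loss at HOXD13 sites stays open. Peaks with a site were kept -1.88 points relative to others, but by score the sites were kept less in 0 of 4 classes and by width in 4 of 4, so the 2 stratifications point in opposite directions and cannot be told apart from these lists.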

How the results depend on the processing

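No paired analysis was possible because the values come from no test and SPDH has 1 library or 1 peak list in each comparison. Of 231 alternative values for 21 genes in mesenchyme, 26 left the counting interval. The settings for resolution, convergence and doublet calls change few cells of this group and the scalings shift all genes alike, by -0.022 for median of ratios, so they test little. Hoxd13 moved to -0.11 with the cluster mix held fixed and to -0.075 over clusters made without the differing genes, and Aldh1a2 to -1.37 with the mix held fixed. Of the other genes, Sulf1 moved by over 1.5 times, to -0.82 in named classes alone; the cause was not tested. Alternatives chosen after seeing the data were the convergence run, other seeds, doublet scores, named classes alone, the second set of clusters and the common score minimum. Among 48 alternative differences for 5 classes, 40 stayed inside the interval. Chondrogenic-like cells moved to -0.59 points without the differing genes, -0.42 at resolution 2.0 and -2.13 with WT clusters and SPDH cells assigned, and turned to 4.38 at resolution 0.5. Distal interdigital-like cells moved to -4.20 at resolution 0.5 and -2.45 at 2.0, and ran from -4.02 to 3.11 over 10 other seeds. Proximal-like cells moved to 0.29 with high doublet scores removed and -1.80 with SPDH cells assigned, and no cluster took that name at 500 or 2000 genes. The convergence run gave -4.14 points for chondrogenic-like cells.

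Of 85 alternative list medians, 59 stayed inside their interval. With members of at least 50 CPM, medians moved to 0.056 for posterior Hoxa, -0.084 for BMP, -0.12 for interdigit and cell death, 0.075 for FGF response, 0.20 for hedgehog, 0.086 for tendon, -0.050 for stress, 0.67 for hemoglobin and 0.027 for mitochondrial genes. Without a filter they moved to 0.18 for hedgehog, 0.060 for cartilage, 0.042 for joint, 0.0010 for hypoxia and glycolysis and 0.061 for mitochondrial genes. Median-of-ratios scaling gave -0.12 for S phase and 0.022 for mitochondrial genes. With the mix fixed, medians were 0.073 for cartilage, 0.053 for joint, 0.075 for tendon, -0.041 for S phase and 0.041 for G2 and M phase, which turned. In named classes alone they were 0.12 for Wnt, -0.16 for cartilage, 0.29 for tendon, 0.026 for mitochondrial genes and 0.016 for G2 and M phase, again turned. Retinoic acid, FGF response, stress, hypoxia and cartilage, which lay inside the random range, also changed sign. Medians left the outer percentiles for posterior Hoxa at 50 CPM, for Wnt (percentile 94.3) and joint (90.2) with the mix fixed, for joint without a filter (61.2) and for G2 and M phase in named classes alone (94.0). Medians passed the outer percentiles for BMP (0.14) and FGF response (98.9) at 50 CPM, for cartilage with the mix fixed (99.8), and in named classes alone for BMP (0.45), cartilage (0), hypoxia (1.79) and stress (98.2). The cause was not tested.

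WT H3K27ac peaks met were 74.5% within 1 kb, 76.0% in the better-scoring 50% of each list, 82.6% at equal numbers and 56.3% at a common score minimum. SPDH H3K27ac peaks met were 91.6%, 93.1%, 85.5% and 98.4% under the same settings. WT H3K27me3 peaks met were 74.3% within 1 kb, 81.8% in the better-scoring 50% and 66.0% at a common minimum, and SPDH peaks 75.1%, 82.0% and 82.7%. The HOXD13 difference was 2.67 points in the better-scoring 50% and -4.49 at a common minimum. H3K27me3 at WT-only H3K27ac peaks was 6.70% within 1 kb and 1.71% in the better-scoring 50%. Chicken SPDH peaks met were 60.9% at 50% overlap of the shorter peak, 65.4% within 1 kb, 71.2% in the better-scoring 50% and 50.9% at equal numbers. Against the shorter list of 1 WT replicate in place of the merged list, 40.4% to 51.0% were met. The cause was not tested.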

Other observations

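Genes below the level set for naming held larger ratios, and those given here were chosen after their values were seen. Irx1, an Iroquois homeobox gene, measured 33.9 CPM of mesenchyme-like cells in WT and 9.42 in SPDH, a log2 ratio of -1.85 (1804 and 440 UMIs). Its neighbour Irx2 was at -1.82 (265 and 66 UMIs), and Inhba, the gene of the activin A subunit, at -1.05 (570 and 241 UMIs). Nr2f1 was at -0.91. Irx3, of the other Iroquois gene cluster, was at 0.84 on 66 and 104 UMIs.

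Genes of the dissociation and stress list had no common direction, with a median log2 ratio of 0.02 at percentile 86.9, or 0.063 at percentile 98.2 without unnamed clusters. Egr1 was at 1.70 and Fos at 0.76, and Jun at 0.34. Hemoglobin UMIs in mesenchyme-like cells were higher in SPDH, with a list median of 0.43 and Hbb-y at 0.67. Over all kept cells Hbb-y was at 0.54 and Hbb-bs at -2.19. Mitochondrially encoded genes had a median of 0.04 at percentile 99.8. A cluster of 98 WT and 82 SPDH cells had a median of 0.049% mitochondrial UMIs and took no class name. The X-linked genes Kdm6a and Jpx, chosen after their values were seen, were at 0.78 and 0.75.

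In the chicken cultures, WT replicate 1 peaks that replicate 2 shared were met by SPDH in 65.3% of 7453 cases, and those it did not share in 20.3% of 11302. SPDH peaks in neither WT replicate were 43.1% of 14099. WT replicate 1 had 48.0% of its peaks in neither of the other lists, and WT replicate 2 had 33.7%.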
